A study of Arabidopsis thaliana with 18 samples.

How the data were processed

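Messenger RNA was sequenced from whole Arabidopsis thaliana seedlings of 3 genotypes: wild type and 2 mutant alleles of ROS1, ros1-3 and ros1-4. ROS1 encodes a DNA glycosylase that removes 5-methylcytosine from DNA. Seedlings 12 d old were kept for 6 h in water with 50 µM of the hormone abscisic acid (ABA) or with its solvent alone (mock). Each of the 6 groups has 3 libraries and each library comes from a pool of 5 plants, per the labels' protocols. RNA was extracted with a column kit and sequenced on an Illumina HiSeq instrument. The labels call the replicates biological, but do not say whether the pools were grown or treated on separate days.

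The deposited values are raw read counts per transcript model, as the authors made them. Per the submitters' processing notes, the tools were Trim Galore 0.2.8, TopHat2 2.0.8, SAMtools and HTSeq 0.6.1, with the TAIR10 genome. The strand setting of the counting is not given in the sources used here, so reads of a gene and of an overlapping antisense gene cannot be told apart. Each file lists 40466 transcript models of 32399 loci, plus 5 summary rows that name no gene. In this counting a read that overlaps several models of a locus goes to the summary row of ambiguous reads, so a locus with several models keeps only the reads that fit 1 model. Ambiguous reads were 32.1% to 33.2% of the sum of ambiguous and counted reads. All rows that name no gene held 36.7% to 44.5% of each file's total, of which multiply aligned reads made 3.5% to 13.0% of the total and reads outside any feature 2.4% to 4.0%. These rows were left out of library sizes and tests. Of the loci, 5883 have more than 1 model, and levels of such loci are understated here: CCA1, LHY, DME, NRPD1 and P5CS1 fell below the count filter in this way or by low expression. Fold changes of such loci rest on the reads that fit 1 model.

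Models were summed per locus. Gene symbols and positions were taken from the TAIR10.1 reference annotation by locus identifier, which matched 31912 of the 32399 loci. Counted reads per library ranged from 3304038 to 10275773. Counts were tested with edgeR 4.0.16 in R 4.3.3: trimmed mean of M values (TMM) scaling, the filterByExpr filter, and the quasi-likelihood F test in 1 fit of all 18 libraries with 1 coefficient per group. The fit tested 15853 genes, 13437 of them with a single model, with 12 residual degrees of freedom and a common biological coefficient of variation of 0.0962. Scaling factors ran from 0.91 to 1.12. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 with no minimum fold. Levels are edgeR's CPM, counts scaled by library size and TMM factor, given as mean ± SD of n = 3 libraries. SE is an approximate standard error: the absolute log2 fold change divided by the square root of its F statistic. Comparisons were ABA against mock within each genotype, each allele against wild type within each treatment, and for each allele the difference between its ABA response and that of wild type (the interaction term). Genes called in the same direction in both alleles were counted as shared. The correlation and covariance of log2 fold changes between the alleles were set beside those of unchanged groups simulated against the same control libraries (20 simulations), which gave almost no calls and thus no reference for the shared counts.

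For a gene with no count in 1 group, the fold is a lower bound computed against 3 counts over that group. With 1 to 3 counts, the ratio is given with its exact 95% counting interval. Bounds and intervals cover counting error only, since reads carry no molecular identifiers.

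Before the data were examined, 20 gene lists were fixed: ABA-responsive genes, clade A PP2C phosphatases, PYR/PYL ABA receptors, ABA kinases and transcription factors, ABA metabolism, NAD synthesis and salvage, DNA methylation and demethylation machinery, earlier published ROS1 targets, photosynthesis, cell cycle, cell wall expansion, hypoxia core genes, salicylic acid and immune genes, jasmonate genes, stomatal lineage, root markers, circadian clock, flavonoid and anthocyanin genes, heat shock genes and seed storage genes. Lists were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison, and again with an estimated correlation. No seed storage gene passed the count filter, which left 19 lists. The rule for named genes was also fixed then. ROS1 is given first. For ABA in wild type, each allele in mock and the interactions, named genes are taken from up to 10 per direction with the largest fold change. Not all of these are named. They must be called, have an average log2 CPM of at least 1 and, in comparisons of 2 groups, show no overlap of libraries between the groups. For the results shared by both alleles, named genes are likewise taken from up to 10 per direction. From each list up to 4 called members with the smallest p are named or, with none called, up to 2 as values. In all comparisons NIC3, EPF2 and RMG1 are also given. EPF2 and RMG1 were linked to ROS1 by earlier work, while NIC3 was chosen on these same plants. NIC3 is nevertheless a member of the list of earlier published ROS1 targets. TMM scaling shares its letters with the gene TMM (TOO MANY MOUTHS); in the results TMM is the gene.

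The steps were tested on simulated counts with 200 genes changed by known folds. For ros1-3 against wild type in mock, on 15561 genes, 46.3% of the 1.5-fold changes, 79.1% of the 2-fold changes and 92.4% of the 4-fold changes were called, and 7 of 152 calls were false. For the interaction term of ros1-3, on 15547 genes, the shares were 16.4%, 35.8% and 86.4%, and 4 of 96 calls were false. Small interactions were thus called less often than large ones. Apart from the planted change, each simulated gene had 1 mean level over all groups. With 200 changed genes the adjusted threshold is easier to pass, so the shares would be lower for a gene that changes alone. Alternatives planned before the data were examined were RLE size factors, no count filter, a stricter filter (50 counts in 3 libraries), DESeq2 1.42.0, a minimum absolute log2 fold change of 1, fits of the compared groups alone, the replicate number as a block, leaving out each library, and for lists an estimated correlation and fry. Added after seeing the data were transcript-model rows as deposited, single-model loci, tests without chromosome 2, the multiply aligned share as a covariate, and the mean of both alleles in 1 contrast. Between replicates of a group, counts differed by more than sampling noise in all pairs, so no library was merged.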

Results

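Messenger RNA levels were measured by counting sequenced reads per gene in 18 libraries of whole Arabidopsis seedlings. The 6 groups of 3 libraries were wild type, ros1-3 and ros1-4, each after 6 h in water with ABA or with solvent (mock). Counted reads per library were 3865324 to 10275773 in wild type mock, 6998339 to 9326824 in wild type ABA and 3304038 to 4271849 in ros1-3 mock. They were 4271674 to 4647380 in ros1-3 ABA, 3920193 to 5096466 in ros1-4 mock and 5591376 to 8824719 in ros1-4 ABA. The share of multiply aligned reads was 9.8% to 13.0% in wild type mock and 6.3% to 11.4% in wild type ABA, 6.5% to 9.5% and 5.6% to 7.5% in ros1-3, and 3.5% to 4.6% and 3.9% to 4.5% in ros1-4. In mock the shares of both alleles lay below those of wild type without overlap, and in ABA so did that of ros1-4. There the share as a covariate cannot fully separate genotype from library differences. The first principal component of log2 CPM held 66.9% of the variance and the next 5.8%. The p-values cover the spread between these pools of plants.

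ROS1, the DNA demethylase that is mutated in both lines, still gave reads in them, at a lower level than in wild type. The gene (AT2G36490) lies on chromosome 2 at 15307907 to 15314807 on the minus strand in the TAIR10.1 annotation. In mock its level was 87.8 ± 6.17 CPM in wild type, 54.1 ± 3.3 in ros1-3 and 34.5 ± 3.57 in ros1-4 (mean ± SD, n = 3 each). In ABA it was 108 ± 11.9, 53.9 ± 5.82 and 40.7 ± 6.2 CPM. ROS1 fell in ros1-3 by a log2 fold change of -0.70 (SE 0.11, edgeR adjusted p = 0.00102) in mock and -1 (SE 0.11, adjusted p = 6.16e-06) in ABA. It fell in ros1-4 by -1.34 (SE 0.12, edgeR adjusted p = 3.68e-07) and -1.40 (SE 0.11, adjusted p = 2.82e-08). The ros1-3 call in mock was lost with the multiply aligned share as a covariate (log2 -0.62, adjusted p = 0.0501 by edgeR, where its alternatives ran from 1.97e-05 to 0.0501). In wild type ROS1 rose slightly with ABA (log2 0.30, SE 0.10, edgeR adjusted p = 0.0257). That call was lost without wild type mock replicate 2 (0.27) or 3 (0.29) and without wild type ABA replicate 2 (0.31) or 3 (0.22). The counts per gene do not show which part of the transcript the reads in the mutants come from.

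The comparison of ABA with mock in wild type asks how seedlings respond to the hormone. The tested ABA-responsive genes rose, and 6 of 8 genes for ABA receptors fell. AT3G17520, a late embryogenesis abundant protein of the kind that accumulates in drying seeds, rose from 0.32 ± 0.0825 to 130 ± 23.8 CPM (log2 8.59, SE 0.38, edgeR adjusted p = 4.74e-14, n = 3). RD29A, a widely used dehydration marker, rose from 14.5 ± 3.74 to 415 ± 51.2 CPM (log2 4.78, SE 0.20, edgeR adjusted p = 2.03e-14). PYL6, an ABA receptor, fell from 24.6 ± 9.06 to 0.392 ± 0.218 CPM (log2 -5.80, SE 0.40, edgeR adjusted p = 9.16e-11). By edgeR 6102 of 15853 genes (38.5%) changed, 3163 higher and 2939 lower. Among the genes with the largest rises, AT5G28520, a mannose-binding lectin, went from 0.251 ± 0.0465 to 68.9 ± 11.2 CPM. Others were absent or nearly absent in mock. AT5G50360 was at least 151-fold higher, NATA1, an acyltransferase, at least 46.7-fold, RD29B at least 39.5-fold and AT5G45690 at least 35.8-fold. The ratio was 1000 (counting interval 180 to 39700) for HAI3, a phosphatase of ABA signalling, 550 (98.3 to 21800) for CSLG2, 417 (74.4 to 16500) for the kinase AT5G24080 and 374 (103 to 3090) for TSPO, a membrane protein. Among the genes with the largest falls, AT3G20380, a TRAF-like protein, had a log2 fold change of -6.21 (SE 0.33), and AT2G28780 one of -6.05 (SE 0.49). The extensin-like cell wall proteins AT1G26240 and AT1G26250 had -5.81 (SE 0.57) and -5.27 (SE 0.27), the acyltransferase AT4G15390 -5.43 (SE 0.40) and the bHLH protein AT2G43140 -5.30 (SE 0.65). CRK30, a receptor-like kinase, was at least 29.5-fold lower. The ratio of mock to ABA was 87.3 (15.2 to 3490) for SLAH1, an anion channel, and 51.2 (13.8 to 430) for TPS13, a terpene synthase.

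All 21 tested ABA-responsive genes rose in wild type (camera adjusted p = 3.08e-92), among them KIN1 (log2 5.80, SE 0.14), ATHB7 (3.92, SE 0.13), ATHB12 (3.02, SE 0.10) and LTI30 (3.83, SE 0.12). All 8 tested clade A PP2C phosphatases, which restrain ABA signalling, rose too (camera adjusted p = 2.09e-58), with HAI2 at 7.30 (SE 0.19), HAI1 at 7.16 (SE 0.19) and ABI1 at 2.54 (SE 0.08). Of 8 PYR/PYL ABA receptors 6 fell, 1 rose and 1 did not pass (camera adjusted p = 1.71e-12). PYL4 fell by -4.09 (SE 0.13), PYL5 by -2.91 (SE 0.15) and PYR1 by -1.70 (SE 0.10), and PYL7 rose by 0.47 (SE 0.13). Of 8 ABA metabolism genes 7 rose and 1 did not pass (camera adjusted p = 2.8e-06). They included NCED3 (log2 2, SE 0.23) and NCED2 (4.18, SE 0.35), which make ABA, and CYP707A4 (4.2, SE 0.36), which breaks it down. These 4 lists kept their call with an estimated correlation. Of 7 ABA kinases and transcription factors 4 rose and 3 did not pass, with ABI5 at 1.70 (SE 0.21) and OST1 at 1.33 (SE 0.22). Its camera adjusted p was 0.0339, and adjusted p = 0.134 with an estimated correlation. Adjusted over the list alone, the counts of these 5 lists were the same.

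Heat shock genes rose in wild type in 5 of 5 cases (camera adjusted p = 0.00096, and adjusted p = 0.134 with an estimated correlation), with the chaperone genes HSP17.4 at log2 2.19 (SE 0.25) and HSP70 at 1.27 (SE 0.15). Of 6 jasmonate genes 5 rose, with LOX2, an enzyme of jasmonate synthesis, at 2.97 (SE 0.30) and the regulator MYC2 at 0.85 (SE 0.09), and PDF1.2b was lower by at least 3.49-fold. The list had a camera adjusted p of 0.0126, and adjusted p = 0.134 with an estimated correlation. Of 5 flavonoid and anthocyanin genes 4 rose and 1 did not pass (camera adjusted p = 0.012, and adjusted p = 0.134 with an estimated correlation). CHS, the entry enzyme of the pathway, rose by 1.33 (SE 0.20) and its regulator TT8 by 2.51 (SE 0.41). Of 13 root markers 8 fell, 1 rose and 4 did not pass (camera adjusted p = 0.00891, and adjusted p = 0.226 with an estimated correlation). The phosphate transporter PHT1;1 fell by -2.78 (SE 0.21) and CASP1, of the endodermal barrier, by -1.72 (SE 0.23). Of 9 genes of cell wall expansion 5 fell, 1 rose and 3 did not pass (camera adjusted p = 0.0406, and adjusted p = 0.226 with an estimated correlation). The expansin EXPA8 fell by -1.73 (SE 0.21) and EXPA3 by -1.17 (SE 0.11), and the cellulose synthase CESA1 rose by 0.36 (SE 0.08). Adjusted over the list alone, 1 root marker rose and 9 fell, 2 cell wall genes rose and 6 fell, and the other 3 lists of this paragraph had the same counts.

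The remaining lists did not pass the camera test in wild type. Of 12 cell cycle genes 5 fell and 7 did not pass (adjusted p = 0.0708 by camera), with PCNA1, of DNA replication, at log2 -1.15 (SE 0.19). Of 21 genes for DNA methylation and demethylation 5 fell, 1 (ROS1) rose and 15 did not pass (0.0761), with the methyltransferases CMT3 at -1.09 (SE 0.17) and MET1 at -0.85 (SE 0.16). Of 21 photosynthesis genes 9 rose, 3 fell and 9 did not pass (0.375), with the antenna gene LHCB2.1 at 1.11 (SE 0.19) and the Rubisco gene RBCS1B at -1.22 (SE 0.14). Of 11 hypoxia genes 5 rose, 1 fell and 5 did not pass (0.17), with ADH1, an enzyme of fermentation, at 2.66 (SE 0.23). Of 10 salicylic acid and immune genes 3 rose, 1 fell and 6 did not pass (0.634), with WRKY33 at 0.33 (SE 0.09) and EDS5 at 0.62 (SE 0.18), calls that were lost with the multiply aligned share as a covariate (0.26 and 0.58). Of 7 clock genes 3 rose and 4 did not pass (0.219), with ELF4 at 1.37 (SE 0.11). Of 8 genes of NAD synthesis and salvage 1 rose, 2 fell and 5 did not pass (0.733), with QS at -0.65 (SE 0.12). Of 10 stomatal lineage genes 1 fell and 9 did not pass (0.234). It was SPCH, a regulator that starts the lineage (-0.84, SE 0.25), and its call was lost without wild type mock replicate 3 or wild type ABA replicate 3 (-0.70 each). Of the 2 tested earlier published ROS1 targets, NIC3 rose and EPF2 did not pass (0.138). Adjusted over the list alone, the counts of these 9 lists were the same.

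**Figure D1:**
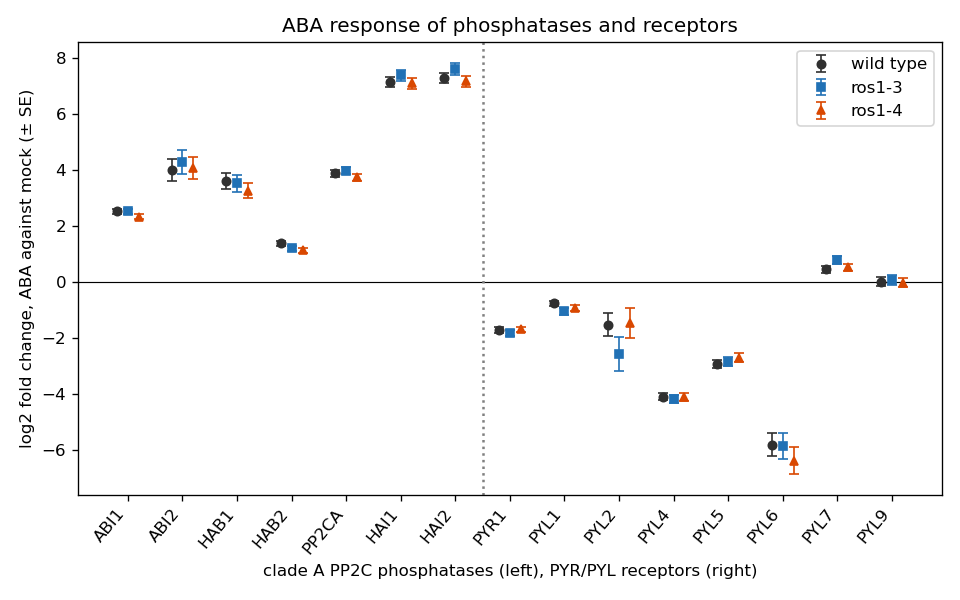
Log2 fold change of ABA against mock for clade A PP2C phosphatases and PYR/PYL ABA receptors in each genotype, with standard errors (n = 3 libraries per group). HAI1 and HAI2 lie highest in wild type, at 7.16 and 7.30, PYL6 lies lowest, at -5.80, and genes with 3 or fewer counts in a group are left out there.

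Both mutants responded to ABA too. By edgeR 6052 genes changed in ros1-3 (3125 higher, 2927 lower) and 6062 in ros1-4 (3142 higher, 2920 lower). All 21 ABA-responsive genes and all 8 PP2C genes rose in both alleles, and 6 of 8 PYR/PYL genes fell and 1 rose in both. The camera adjusted p of these lists was 1.71e-96, 1.76e-52 and 6.75e-12 in ros1-3 and 1.46e-93, 1.89e-54 and 7.17e-13 in ros1-4, and all 3 kept their call with an estimated correlation. Adjusted over the list alone, their counts were the same. Wild type and ros1-3 shared 4703 genes changed in the same direction, where independent lists would share 624 higher and 543 lower, and 3 genes changed in opposite directions. Wild type and ros1-4 shared 4809, with 0 opposite by the same edgeR calls. In all 3 genotypes 4201 genes changed in the same direction, 2317 higher and 1884 lower. Across genes, which are not independent replicates, the log2 fold changes of wild type correlated with those of ros1-3 at r = 0.92 and with those of ros1-4 at r = 0.931. NIC3, a nicotinamidase of NAD salvage, went from 4.96 ± 2.25 to 33.4 ± 2.48 CPM in wild type (log2 2.88, SE 0.23, edgeR adjusted p = 1.15e-09), from 4.84 ± 0.573 to 6.92 ± 0.468 in ros1-3 (0.53, SE 0.31, adjusted p = 0.195) and from 6.48 ± 1.8 to 11.3 ± 2.75 in ros1-4 (0.80, SE 0.25, adjusted p = 0.0125). The ros1-4 call was lost without ros1-4 mock replicate 2 (0.65) or ros1-4 ABA replicate 3 (0.66), and the test of the difference between genotypes did not pass over all genes in either allele (edgeR adjusted p = 0.0746 and 0.0947). EPF2 was at -0.43 (SE 0.24) in wild type, which did not pass, and fell by -1.14 (SE 0.36) in ros1-3 and -2.01 (SE 0.66) in ros1-4. Its calls were lost without ros1-3 mock replicate 3 (-1) or ros1-3 ABA replicate 3 (-0.85), and without ros1-4 mock replicate 1 (-1.54) or ros1-4 ABA replicate 2 (-1.6).

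The comparison of ros1-3 with wild type in mock asks which genes differ in this allele without added hormone. Most of the changed genes were lower in the mutant, and many lie on chromosome 2, which also carries ROS1. SEH, a soluble epoxide hydrolase, fell from 242 ± 12.9 to 10.5 ± 1.1 CPM (log2 -4.52, SE 0.17, edgeR adjusted p = 5.26e-14, n = 3). AT2G35810, annotated as ureidoglycolate hydrolase, rose from 22.9 ± 4.32 to 130 ± 11.3 CPM (log2 2.54, SE 0.12, edgeR adjusted p = 4.04e-12). Both also differed between the alleles in mock, with ros1-3 against ros1-4 at log2 -4.52 for SEH and 2.35 for AT2G35810. These changes thus belong to ros1-3 and were not shared by ros1-4. AT2G33830, a dormancy and auxin associated protein, fell from 1300 ± 72 to 117 ± 21.2 CPM (log2 -3.48, SE 0.14, edgeR adjusted p = 2.65e-13). By edgeR 210 genes changed, 49 higher and 161 lower. On chromosome 2 lay 92 of them (43.8%), beside 2402 of the 15853 tested genes (15.2%; Fisher's exact test, two-sided, p = 1.45e-23). Between 9 and 16 Mb of that chromosome, a window chosen after the calls were seen, 69 of 1047 tested genes (6.59%) were called, against 141 of 14806 (0.95%) elsewhere. Among the largest falls AT2G23330 was at least 38.9-fold lower, AT2G21840 at least 12.6-fold and AT2G24755 at least 12.2-fold. The ratio of wild type to mutant was 67.7 (11.9 to 2700) for TO1, a thioredoxin, 46.9 (8.15 to 1880) for AT2G30945 and 16.6 (4.37 to 141) for GLTP1, a glycolipid transfer protein. AT2G21080 fell by log2 -3.66 (SE 0.20) and AT2G21850 by -3.88 (SE 0.48). Among the largest rises were AT1G47395 (4.26, SE 0.68), ALB3, a protein of thylakoid assembly (2.87, SE 0.44), and AT2G25964 (1.88, SE 0.15). TMM, a receptor-like protein that patterns stomata, rose by 0.76 (SE 0.11), and EPF2, a peptide that limits the stomatal lineage, was at -0.71 (SE 0.28, edgeR adjusted p = 0.275). NIC3 was at 0.09 (SE 0.32, edgeR adjusted p = 0.954). The stomatal list as a whole did not pass (camera adjusted p = 0.0897), with 1 of 10 members called and 2 higher adjusted over the list alone. Cell wall expansion passed in the lower direction (camera adjusted p = 0.00073, and adjusted p = 0.217 with an estimated correlation), with 0 higher, 1 lower and 8 not passed by edgeR and 3 lower adjusted over the list alone. The called member was XTH4, a wall enzyme (-0.43, SE 0.10), whose call was lost without wild type mock replicate 3 (-0.36) and without ros1-3 mock replicate 1 (-0.35) or 3 (-0.41), and with the multiply aligned share as a covariate (-0.50). With the covariate the XTH4 value did not shrink, so that loss does not show that the difference was removed. The cell cycle list passed in the higher direction (camera adjusted p = 0.0276, and adjusted p = 0.78 with an estimated correlation), with 0 of 12 members called by edgeR and 2 higher adjusted over the list alone. Without ros1-3 mock replicate 1 the count of changed genes was 105, and without replicate 3 it was 107. With the multiply aligned share as a covariate, a setting chosen after seeing the data, it was 98. That share did not overlap between ros1-3 and wild type in mock, so the setting cannot fully separate it from genotype.

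**Figure D2:**
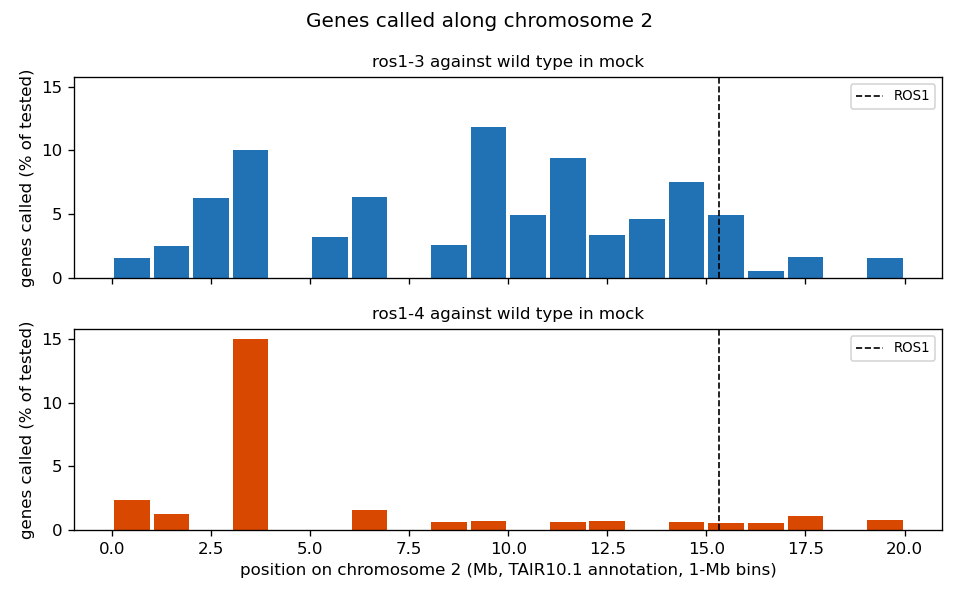
Share of tested genes called against wild type in mock, in percent, per megabase of chromosome 2, for ros1-3 and ros1-4, with the position of ROS1. Between 9 and 16 Mb, a window chosen from the ros1-3 calls, 6.59% of tested genes were called in ros1-3 and 0.478% in ros1-4, and the tall ros1-4 bar at 3 to 4 Mb holds 3 of 20 tested genes.

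The comparison of ros1-4 with wild type in mock asks the same of the other allele. Fewer genes changed, most of them lower. MSRB5, a methionine sulfoxide reductase, fell from 35.6 ± 8.35 to 5.02 ± 0.952 CPM (log2 -2.81, SE 0.22, edgeR adjusted p = 8.32e-08, n = 3), and AT2G33830 fell to 151 ± 25.7 CPM (log2 -3.11, SE 0.14, adjusted p = 3.23e-12). EPF2 fell from 7.01 ± 1.28 to 1.02 ± 0.494 CPM (log2 -2.78, SE 0.36, edgeR adjusted p = 8.27e-05), and TMM rose from 36.6 ± 2.67 to 87.2 ± 4.53 CPM (log2 1.25, SE 0.10, adjusted p = 2.1e-07). HAK5, a potassium transporter, rose by 1.5 (SE 0.22) and SWEET1, a sugar transporter, by 1.11 (SE 0.18). CPK22 also rose, but its call was lost without any 1 of 4 libraries, at values of 2.85 to 3.12. AT5G17165 lost its call in the same way without any 1 of 4 (1.53 to 1.66), and AT2G47880 without any 1 of 3 (1 to 1.57). BGLU35, a beta-glucosidase, fell by -5.07 (SE 0.63) and the RNA AT1G15405 by -2.82 (SE 0.35), and the ratio of wild type to mutant for AT1G62760, related to invertase inhibitors, was 36.8 (9.91 to 308). NIC3 was at 0.54 (SE 0.29, edgeR adjusted p = 0.764). By edgeR 71 genes changed, 17 higher and 54 lower, and 18 of them (25.4%) lay on chromosome 2 (Fisher's exact test, two-sided, p = 0.0289). From the calls that were lower, 5 ribosomal or organelle-type loci were set apart, so their direction is fixed by the choice. Among them were AT3G41768 (-2.28, SE 0.24) and AT2G07732 (-2.82, SE 0.28). Of the other 66 calls 14 (21.2%) lay on chromosome 2 (p = 0.169 by the same exact test). Only called loci of this class were set apart, so the higher p does not show that the class accounts for the excess. The multiply aligned share of the ros1-4 mock libraries differed from that of wild type by log2 -1.56. With that share as a covariate 11 genes were called. The calls of AT2G33830 (log2 -3.03), MSRB5 (-2.72) and AT1G62760 were among them, and those of EPF2 (-2.87, edgeR adjusted p = 0.0643), TMM (0.86, adjusted p = 0.0947), HAK5 (1.95), SWEET1 (0.69), BGLU35 (-2.97) and AT1G15405 (-1.4) were lost. The values of EPF2 and HAK5 did not shrink, so their lost calls do not show that these differences were removed. The values of the other lost calls shrank. The adjusted p over all alternatives ran from 2.59e-07 to 0.0643 for EPF2 and from 2.85e-21 to 0.0947 for TMM by edgeR or DESeq2. Without ros1-4 mock replicate 2 the count was 47.

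Stomatal lineage genes were higher as a list in ros1-4 in mock (camera adjusted p = 2.01e-05, and adjusted p = 0.0213 with an estimated correlation), with 1 higher, 1 lower and 8 not passed by edgeR, and 3 higher and 1 lower adjusted over the list alone. SPCH was at log2 0.96 (SE 0.23, edgeR adjusted p = 0.0709). The earlier published ROS1 targets, of which only EPF2 and NIC3 were tested, passed as lower (camera adjusted p = 0.00319, and adjusted p = 0.0389 with an estimated correlation). EPF2 was lower, while NIC3 did not pass and lay in the higher direction, with the same count adjusted over the list alone. The pass of the list thus rests on EPF2. This list was chosen from work on ROS1 mutants, with NIC3 chosen on these same plants, and is not independent evidence of its direction. Cell wall expansion passed as lower (camera adjusted p = 0.0497, and adjusted p = 0.476 with an estimated correlation), although its median was 0.01 and its mean -0.20. Its called member, EXPA8, fell by -1.54 (SE 0.21), with 8 not passed and 2 lower adjusted over the list alone, and the EXPA8 call was lost with the covariate (-2.08). That value did not shrink, so the lost call does not show that the EXPA8 difference was removed. The DNA methylation list, with ROS1 lower and 20 not passed, and 1 lower adjusted over the list alone, passed as lower with a median of 0.03 and a mean of -0.11 (camera adjusted p = 0.036, and adjusted p = 0.509 with an estimated correlation). ROS1 is itself the mutated gene, so this pass is not independent of the genotype. No member was called by edgeR in 5 further lists that passed camera. Heat shock genes were lower (camera adjusted p = 0.00319, and adjusted p = 0.327 with an estimated correlation), with 3 lower adjusted over the list alone. The others had 0 members called adjusted over the list alone by edgeR. Hypoxia genes were lower (camera adjusted p = 0.0193, and adjusted p = 0.509 with an estimated correlation). Clock genes were lower (camera adjusted p = 0.0193, and adjusted p = 0.327 with an estimated correlation). Root markers were lower (camera adjusted p = 0.036, and adjusted p = 0.509 with an estimated correlation). Cell cycle genes were higher (camera adjusted p = 0.0308, and adjusted p = 0.509 with an estimated correlation).

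**Figure D3:**
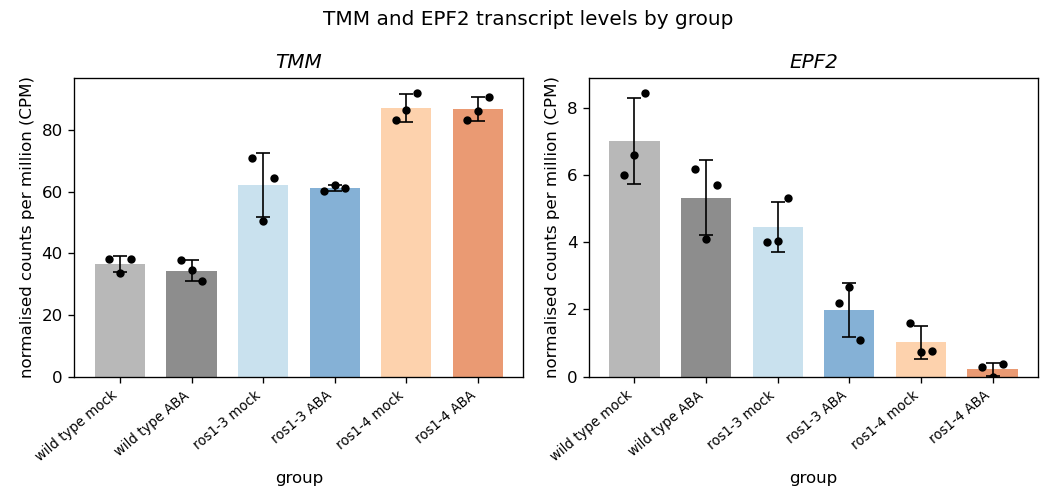
Levels of TMM and EPF2 in normalised CPM for each library (points), with bars at the mean and error bars of 1 SD of each group (n = 3). TMM averages 36.6 and 34.4 in wild type and 87.2 and 86.8 in ros1-4, and EPF2 averages 7.01 and 5.32 in wild type and 1.02 and 0.215 in ros1-4.

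In mock 36 genes changed in the same direction in both alleles, 4 higher and 32 lower, and 0 in opposite directions by edgeR. TMM, the disease resistance-like AT4G19520 (log2 0.91 in ros1-3 and 0.95 in ros1-4), AT4G23670 (0.55 and 0.78) and AT1G69160 (0.51 and 0.44) were the 4 that rose. AT2G33830 fell in both, as did HEI10, of meiotic crossover formation (-2.76, SE 0.36, and -1.94, SE 0.31), MSRB5 (-1.54, SE 0.20, and -2.81, SE 0.22) and AT3G27980 (-3.04, SE 0.47, and -2.83, SE 0.43). AT5G38550, a mannose-binding lectin, was lower by a ratio of 14.5 (4.77 to 72.3) in ros1-3 and at least 17.1-fold in ros1-4, calls that were lost with DESeq2. Independent lists would share 0.053 higher and 0.55 lower genes. The 3 control libraries could not be divided between the alleles, so both alleles were set against the same controls, and their log2 fold changes over all tested genes correlated at r = 0.39, where 20 simulations of unchanged groups against shared controls gave 0.44, with a covariance of 0.0467 observed and 0.0301 simulated. The ros1-4 call of AT1G69160 was lost without any 1 of the 6 libraries, at 0.39 (wild type mock replicate 1), 0.48 (2) and 0.46 (3), and at 0.44 (ros1-4 mock replicate 1), 0.46 (2) and 0.42 (3), and its ros1-3 call without ros1-3 mock replicate 3 (0.45). The ros1-3 call of AT4G23670 was lost without wild type mock replicate 2 (0.44) and without ros1-3 mock replicate 1 (0.51) or 3 (0.50). The count was 21 without ros1-3 mock replicate 1, 22 without replicate 3, and 6, all lower, with the multiply aligned share as a covariate. That setting ended the ros1-4 calls of HEI10 (-1.71), AT3G27980 (-2.47), AT5G38550, AT4G19520 (1), TMM (0.86), AT4G23670 (0.38) and AT1G69160 (0.31), and the ros1-3 calls of AT4G23670 (0.35), AT1G69160 (0.45) and AT5G38550. In ros1-4 HEI10, AT3G27980 and AT4G19520 stayed near their values without it, so the lost calls do not show that these differences were removed. Nor do those of AT5G38550, for which no fitted value is given because it had 3 and 0 counts in the mutants.

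Under ABA, NIC3 and ILA fell in both alleles and TMM rose in both. NIC3 had 33.4 ± 2.48 CPM in wild type, and fell by log2 -2.26 in ros1-3 (SE 0.22, edgeR adjusted p = 8.92e-07) and by -1.53 in ros1-4 (SE 0.19, adjusted p = 5.7e-05, n = 3). ILA, a protein of plant immunity, fell from 9.35 ± 0.487 CPM by -4.85 (SE 0.43, edgeR adjusted p = 1.37e-07) and -4.08 (SE 0.34, adjusted p = 7.39e-08). EPF2 fell by -1.43 (SE 0.33, edgeR adjusted p = 0.023) and -4.36 (SE 0.44, adjusted p = 2.29e-06), and TMM rose by 0.82 (SE 0.11) and 1.33 (SE 0.10). The ros1-3 call of EPF2 was lost without wild type ABA replicate 1 (-1.29) or 3 (-1.39) and without ros1-3 ABA replicate 1 (-1.5) or 3 (-1.13). By edgeR 273 genes changed in ros1-3 (117 higher, 156 lower) and 108 in ros1-4 (32 higher, 76 lower). In the same direction in both were 36 (10 higher, 26 lower), and 2 in opposite directions. Independent lists would share 0.24 higher and 0.75 lower genes, and the 2 sets of log2 fold changes correlated at r = 0.4, where simulated unchanged groups gave 0.44, with a covariance of 0.046 observed and 0.0245 simulated. Others that fell in both were AT2G33830 (-3.38, SE 0.14, and -3.06, SE 0.14) and AT1G08940, of the phosphoglycerate mutase family (-2.57, SE 0.23, and -2.44, SE 0.21). AT4G04410 rose in both (1.73, SE 0.26, and 1.56, SE 0.25), and its ros1-4 call was lost with the multiply aligned share as a covariate, at a similar value (1.5). Of the ros1-3 calls 105 lay on chromosome 2 (38.5%, Fisher's exact test, two-sided, p = 2.27e-21), and of the ros1-4 calls 22 (20.4%, p = 0.138 by the same exact test). The ros1-3 count was 158 and 146 without wild type ABA replicate 2 and 3, and 169, 155 and 138 without ros1-3 ABA replicate 1, 2 and 3. The ros1-4 count was 65 without wild type ABA replicate 3 and 44 with the covariate.

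Among the lists under ABA the stomatal lineage was higher in both alleles, in ros1-3 with a camera adjusted p of 0.000614, and adjusted p = 0.0489 with an estimated correlation, and in ros1-4 with 8.02e-07, and adjusted p = 0.00575 with an estimated correlation. Its members were 1 higher, 1 lower and 8 not passed in ros1-3 and 2 higher, 1 lower and 7 not passed in ros1-4, and adjusted over the list alone 5 higher and 1 lower in each. POLAR, a marker of the lineage, was at log2 1.14 (SE 0.39) and 1.18 (SE 0.36), and neither passed over all genes. SDD1 rose in ros1-4 (0.93, SE 0.22), a call lost without wild type ABA replicate 2 (1.05) or 3 (0.68) and ros1-4 ABA replicate 1 (0.86) or 3 (0.82), and with the multiply aligned share as a covariate (0.59, edgeR adjusted p = 0.812, where its alternatives ran from 0.0024 to 0.812). The 2 earlier published ROS1 targets fell in both alleles (camera adjusted p = 1.97e-10 and 1.54e-20, kept with an estimated correlation), with the same counts adjusted over the list alone and the same limit as independent evidence. Cell wall expansion was lower in ros1-3 (camera adjusted p = 7.54e-06, and adjusted p = 0.0335 with an estimated correlation), with 1 of 9 members lower, XTH4 (-0.59, SE 0.10), and 6 lower adjusted over the list alone. Cell cycle genes were higher in ros1-3 (camera adjusted p = 5.03e-05, and adjusted p = 0.219 with an estimated correlation), with 1 of 12 higher and 7 adjusted over the list alone. The called member, CDKB2;1 (0.76, SE 0.16), was lost without wild type ABA replicate 2 (0.71) or ros1-3 ABA replicate 2 (0.67). ABA-responsive genes were higher in ros1-3 (camera adjusted p = 5.05e-05, and adjusted p = 0.19 with an estimated correlation), with 2 of 21 higher, also adjusted over the list alone. One of them was RD20, a caleosin, at 0.91 (SE 0.16). In ros1-4 they were lower (camera adjusted p = 0.0448, and adjusted p = 0.558 with an estimated correlation), with 0 of 21 called by edgeR and 2 lower adjusted over the list alone. Photosynthesis genes were lower in ros1-3 (camera adjusted p = 0.000953, and adjusted p = 0.516 with an estimated correlation), with 1 of 21 lower and 3 adjusted over the list alone. Flavonoid genes were higher in ros1-3 (camera adjusted p = 0.0267, and adjusted p = 0.219 with an estimated correlation), with 1 of 5 higher in both counts, all genes and adjusted over the list alone. Salicylic acid and immune genes were higher in ros1-4 (camera adjusted p = 0.0027, and adjusted p = 0.033 with an estimated correlation), with 0 of 10 called by edgeR in either count. Hypoxia genes were lower in ros1-4 (camera adjusted p = 0.00253, and adjusted p = 0.395 with an estimated correlation), with 0 of 11 called by edgeR in either count. Heat shock genes were lower in ros1-4 (camera adjusted p = 0.00606, and adjusted p = 0.395 with an estimated correlation), with 0 of 5 called by edgeR and 1 lower adjusted over the list alone.

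The interaction terms ask whether a mutant's response to ABA differs from that of wild type. NIC3 (AT5G23220, chromosome 5, 7819608 to 7820760, minus strand) had the clearest value, with an ABA response lower by log2 -2.35 in ros1-3 (SE 0.40, edgeR adjusted p = 0.0746) and by -2.07 in ros1-4 (SE 0.35, adjusted p = 0.0947), so that it did not pass in either. Over 21 alternatives each, it was called in 5 for ros1-3 (adjusted p 0.000609 to 0.266 by edgeR or DESeq2) and in 3 for ros1-4 (0.000476 to 0.933). Adjusted over the list alone, NIC3 was the 1 gene called among 8 NAD genes in both alleles (edgeR adjusted p = 6.08e-05 and 4.78e-05). NIC3 was chosen on these same plants, so the adjustment over this list is no independent support. EPF2 was at -0.72 (SE 0.44) and -1.58 (SE 0.70), and ROS1 at -0.30 (SE 0.16) and -0.06 (SE 0.16). By edgeR 0 genes passed for ros1-3 and 0 for ros1-4, with 743 and 521 at an unadjusted p under 0.05, where chance gives 793. DESeq2 called 11 and 1. The shared count was 0 by edgeR and 1 by DESeq2. The count for ros1-3 was 6 without wild type ABA replicate 1, 3 without wild type mock replicate 1, 3 without replicate 3 and 1 without replicate 2. The count for ros1-4 was 2 without wild type ABA replicate 3 and 1 without wild type mock replicate 2, which also gave a shared count of 1. The 2 earlier published ROS1 targets were lower in both terms (camera adjusted p = 1.59e-06 and 3.63e-08, with adjusted p = 0.0031 and 0.00111 with an estimated correlation), with 1 and 2 lower adjusted over the list alone, and are not independent evidence. Jasmonate genes were higher in ros1-3 (camera adjusted p = 0.00206, and adjusted p = 0.143 with an estimated correlation), with 0 of 6 called by edgeR and 1 higher adjusted over the list alone. Hypoxia genes were lower in ros1-3 (camera adjusted p = 0.0348, and adjusted p = 0.826 with an estimated correlation), with 0 of 11 called by edgeR in either count. RMG1, another reported ROS1 target, had 35 counts over all libraries and was not tested.

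**Figure D4:**
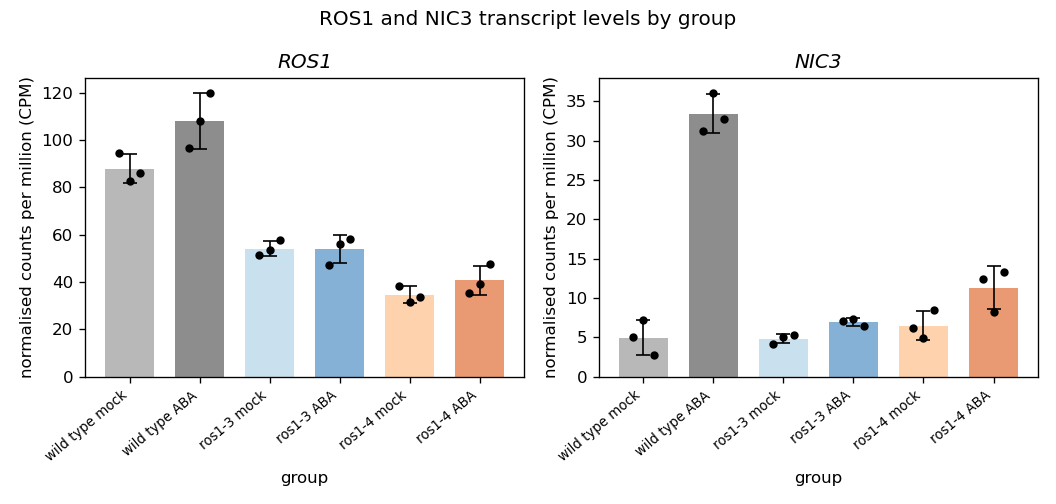
Levels of ROS1 and NIC3 in normalised CPM, 1 point per library, with bars at the mean and error bars of 1 SD (n = 3 per group). NIC3 averages 33.4 in wild type ABA, 6.92 in ros1-3 ABA and 11.3 in ros1-4 ABA.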

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

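All tests of explanations in this part were chosen after the results were seen, while the splits of the libraries were planned before. In each comparison of 2 groups 3 libraries against 3 give 10 splits, too few for a share under 0.05. The real counts and the highest of the other splits were 6102 and 0 for ABA in wild type, 6052 and 0 in ros1-3 and 6062 and 0 in ros1-4. They were 210 and 8 for ros1-3 in mock, 71 and 2 for ros1-4 in mock, 273 and 0 for ros1-3 in ABA and 108 and 12 for ros1-4 in ABA. For the genes shared by both alleles 1 of 60 splits, the real one, was as large in either treatment. The count was 36 in mock (highest other 1) and 36 in ABA (highest other 34). At 0.05 this argues against libraries that do not differ by genotype at all. The splits shuffle genotypes, so they do not test whether the alleles share more genes than their common controls would produce. The split that gave 34 exchanged whole genotypes within ABA. For the interaction terms, with 0 genes by edgeR (743 and 521 at an unadjusted p under 0.05, 11 and 1 by DESeq2), 60 of 60 splits were as large. A real count of 0 makes this so by construction, so these splits say nothing about chance. Single splits called up to 154 and 218 genes. These mixed or exchanged genotypes in 1 treatment only, which points to the structure of the samples: differences between genotypes then appear as interactions. The same holds for the shared interaction (0 by edgeR, 1 by DESeq2), where all 60 splits were as large, with a highest of 19. For the total of 56 list tests that passed, 23 of 60 splits were as large, with a highest of 83, so chance is not excluded for this total. These splits mixed ABA with mock libraries and the total pools all 9 comparisons, so they say nothing about any 1 list or about the ABA lists alone.

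The alleles differed from each other. A direct test of ros1-3 against ros1-4 by edgeR called 201 genes in mock (84 higher, 117 lower) and 442 in ABA (201 higher, 241 lower), with 41.3% and 30.5% of them on chromosome 2. In both treatments SEH was lower in ros1-3 (log2 -4.52 and -4.33) and AT2G35810 higher (2.35 and 2.29).

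Of the ros1-3 calls in mock 43.8% lie on chromosome 2, and of the ros1-4 calls 25.4% (Fisher's exact test, p = 0.0289), beside 15.2% of tested genes. Without 5 ribosomal and organelle-type loci the ros1-4 share was 21.2% (p = 0.169 by Fisher's exact test). Those loci were picked among the calls, so the higher p does not show that they account for the ros1-4 excess. An effect of the loss of ROS1 that acts alike on all chromosomes is argued against by the ros1-3 share (Fisher's exact test, p = 1.45e-23). Reads of another strain that fail to align would lower the count of their gene. They do not by themselves explain the 23 chromosome 2 genes that were higher, and other effects of strain differences on counting were not tested. For the lower genes the share of lower calls did not differ from that elsewhere (Fisher's exact p = 0.626). Failed alignment thus cannot be told apart from lower expression for them. A candidate explanation is a segment linked to ROS1 that came from another strain, where a window of 9 to 16 Mb, chosen from the ros1-3 calls themselves, had 6.59% of genes called in ros1-3 and 0.478% in ros1-4. The choice of window favours ros1-3 and the labels do not give the strain in which ros1-3 arose, so it stays a hypothesis.

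From the loci called lower in ros1-4 in mock, 5 ribosomal and organelle-type loci were taken, so their direction was fixed by the choice. Their median log2 fold change was -2.36. Carry-over of ribosomal and organelle RNA that differs between libraries may account for most of it, since the trend on the multiply aligned share within groups predicts a median of -1.87. The same trend predicted at least 50% of the change in 12 of the 66 other ros1-4 calls. It was fitted within groups and extended, without an error, to a group difference of log2 -1.56. It thus does not decide whether carry-over is a common cause of these 66 calls. With the share as a covariate the median of the 5 ribosomal and organelle-type loci was -0.84. Because the shares of ros1-4 and wild type libraries do not overlap, genotype and library preparation cannot be told apart for these loci. In mock the shares of ros1-3 (6.5% to 9.5%) and wild type (9.8% to 13.0%) do not overlap either. The same limit holds for the other ros1-4 calls and for the ros1-3 calls in mock when the share is a covariate.

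NIC3 responded less to ABA in the mutants, with a difference of log2 -2.21 for the mean of both alleles (SE 0.31, edgeR adjusted p = 0.00725), a contrast chosen after seeing the data. Reads moved to the neighbouring copy NIC2 are argued against by 5.12 CPM of NIC2 in ros1-3 ABA, where the missing reads would give 33.1. Lower depth is argued against because the lowest wild type level would give 128 counts in the smallest ros1-3 ABA library, where the highest count found was 33. The scaling left the ros1-3 difference at -2.34 with RLE size factors. Loss of ROS1 in both alleles may account for it, as a hypothesis found and tested on the same data.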

How the results depend on the processing

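The multiply aligned share as a covariate, the tests without chromosome 2, those on transcript models or single-model loci and the mean of both alleles were chosen after seeing the data. Over 8315 values of named genes under alternatives, 7804 kept their direction and side of the threshold, 459 lost a call, 27 gained one, 25 without a call moved and 0 reversed. Over 684 list tests these numbers were 608, 53, 20, 3 and 0. An absolute log2 fold change of at least 1, which by construction lowers counts, left 2098, 2220 and 2070 genes for ABA in wild type, ros1-3 and ros1-4. It left 82 for ros1-3 in mock, 96 and 57 for ros1-3 and ros1-4 in ABA, and 23 shared genes in mock and 23 in ABA. With no low-count filter the counts were 333 and 108 in mock for ros1-3 and ros1-4, 202 for ros1-4 in ABA, 16 and 3 for the interactions, 66 shared in ABA and 1 shared interaction. DESeq2 called 11 and 1 genes for the interactions and 1 shared. With the covariate 98 and 11 genes were called in mock for ros1-3 and ros1-4, 44 for ros1-4 in ABA, 4 for the ros1-3 interaction and 6 shared in mock. Without chromosome 2 the counts were 87 for ros1-3 in mock and 132 in ABA, with fewer genes tested. The mean of both alleles in 1 contrast called 128 genes in mock, 138 in ABA and 1, NIC3, for the interaction. Such a contrast can also call a gene changed in 1 allele alone. SEH in mock was called at a mean of -2.26, while ros1-3 against ros1-4 was at -4.52. With an estimated correlation 22 list tests passed in place of 56. Beyond the fewer genes tested or called by construction, the cause was not tested.

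Leaving out 1 library at a time gave 5233 to 5605 genes for ABA in wild type, 5139 to 5718 in ros1-3 and 5094 to 5578 in ros1-4. The ranges were 105 to 285 for ros1-3 and 47 to 68 for ros1-4 in mock, 138 to 302 and 65 to 104 in ABA, 0 to 6 and 0 to 2 for the interactions, and 21 to 35, 27 to 39 and 0 to 1 for the shared results. With the replicate number as a block the counts were 5864, 5904 and 5878 for ABA, 178 and 64 in mock, 232 and 96 in ABA, and 0 and 0 for the interactions by edgeR. The numbers do not pair the samples: 4 of 18 libraries correlated best with a library of their own number, and the mean r of same-number pairs was -0.021. With 3 libraries per group, simulated 2-fold differences of the ABA response of ros1-3 were called in 35.8% of cases.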

Other observations

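By edgeR 21 genes changed in the same direction in all 4 comparisons of a mutant with wild type, 2 higher (TMM and AT1G69160) and 19 lower. Without 1 library at a time the count was 14 to 20. With the multiply aligned share as a covariate it was 6, all lower, and 5 of these were among the 21, which kept their signs in all 4 comparisons. That setting ended the ros1-4 calls of TMM (0.86) and AT1G69160 (0.31) in mock and the ros1-3 call of AT1G69160 (0.45), whose ros1-4 call in mock was also lost without any 1 of the 6 libraries (0.39 to 0.48) and its ros1-3 call without ros1-3 mock replicate 3 (0.45). The names below were chosen after their values were seen. FDH, a formate dehydrogenase, was at log2 -1.59 and -0.90 in ros1-3 and ros1-4 in mock and -0.96 and -0.58 in ABA. PMAT2, an acyltransferase, was at -1.30, -0.87, -1.55 and -0.83 in the same order, MSS3, a calcium-binding protein, at -0.48, -0.69, -0.57 and -0.77, and ZW9, a TRAF-like protein, at -2.32, -1.86, -1.39 and -2.28. With the covariate the ros1-4 calls in mock of FDH (-0.96), PMAT2 (-0.73) and MSS3 (-0.87) were lost, and that of PMAT2 in ABA (-0.76). The values of FDH and MSS3 did not shrink, so their lost calls do not show that these differences were removed. The ros1-3 call of MSS3 in mock was lost without wild type mock replicate 2 (-0.49) or 3 (-0.45) or ros1-3 mock replicate 1 (-0.42) or 3 (-0.5), and the ros1-4 call of PMAT2 in mock without ros1-4 mock replicate 3 (-0.72). Pseudogenes made 0.568% of tested genes and 3.33%, 7.04%, 2.56% and 8.33% of the calls in these comparisons (7, 5, 7 and 9 genes).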
